A study of Mus musculus with 8 samples.

How the data were processed

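The data are RNA-seq libraries of cDC1 and cDC2 that were sort-purified from the spleens of C57BL/6 mice, untreated, with 100000 cells per sample, per the labels' protocols. RNA was isolated with the NucleoSpin RNA XS kit, 10 ng of total RNA with an integrity score above 8.0 went into the SMARTer Ultra Low RNA kit, which does not mark strand, and libraries were sequenced on a NovaSeq X Plus with paired reads of 150 bases, per the labels' protocols. The sort gates, the number of animals per library and the meaning of the replicate numbers are not given in the sources used here.

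Per the submitters' processing notes, the authors used bcl2fastq, STAR, Subread featureCounts and Salmon with the builds GRCm38 and mm10; the order of these steps, the strand setting and the handling of reads shared between genes are not stated. Each library has its own file with 55487 Ensembl genes. The deposited count column holds whole numbers of reads per gene, per the file headers. The deposited CPM column is the count over the column's total, scaled to 1000000, which was checked on the values. The deposited FPKM column is that CPM per kilobase of the exon length given for the gene, which was also checked. The deposited TPM column was not used. Only the counts were used for the tests, and the authors' CPM and FPKM values only for these checks. Gene symbols came from the GENCODE M21 annotation of GRCm38, which held 55227 of the gene IDs, 54870 of them with identical coordinates; 260 IDs had no match and kept their ID. Coordinates are those of the files.

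Counts were fitted in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with the 4 groups (20631 genes) and libraries were scaled with TMM. A quasi-likelihood model with robust estimation was fitted with 1 coefficient per group over all 8 libraries, so that the 4 residual degrees of freedom are shared. The common biological coefficient of variation was 0.286. The 5 comparisons were wild-type cDC1 minus wild-type cDC2, Zeb2 mutant cDC1 minus wild-type cDC1, Irf8 mutant cDC2 minus wild-type cDC2, Zeb2 mutant cDC1 minus Irf8 mutant cDC2, and the Zeb2 mutant's effect minus the Irf8 mutant's effect. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison. Standard errors are the size of the log2 fold change over the square root of its F statistic. Folds are ratios of mean TMM-normalised CPM; where a group had no count they are lower bounds against 3 counts over the group, and with 1 to 3 counts no fold is given. These floors cover counting error only, and the p-values measure only the spread between these samples, since what a replicate stands for is not stated.

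The main test, the comparisons, 25 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Of the lists 24 were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 24 lists of a comparison, 120 tests in all; beside each call stands the adjusted p with a correlation estimated from the residuals, and fry was run as a further set test. A call lost with the estimate does not by itself show that genes move together. For ESAM-high cDC2 genes in the Zeb2 mutant comparison the estimate was -0.099, below the preset, yet camera's unadjusted p rose from 0.00951 to 0.0537. Counts of list members are given over all genes and adjusted over the list alone. Mb21d1 was the only list gene without an ID. The list of sex genes served as a check of the libraries: in every library Xist was at most 0.073 CPM and Ddx3y at least 114 CPM. Named genes were the 10 largest changes per direction among called genes with both libraries of a group above both of the other and at least 5 CPM in the higher group. Added to these were up to 4 called members per list (or the 2 most abundant where none was called), Irf8 and Zeb2, and the 5 smallest adjusted p-values of the difference of effects. Predicted genes, pseudogenes, receptor segments, mitochondrial and histone genes were skipped as names but counted. Some called or listed genes enter every count but are not reported here. For other list members given as examples, values were seen first. Genes near a target were counted within 1000000 bases of the gene body.

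The model was tested on simulated counts with 200 genes changed. They were drawn from each gene's mean over all 8 libraries, its fitted dispersion and the real library sizes, without differences between cell types or a length trend. In the comparison of Zeb2 mutant and wild-type cDC1, of changed genes at 10 CPM or more it recovered 0% at 1.5-fold, 81.0% at 2-fold and 94.2% at 3-fold, and over all 200 changed genes 34.5% at 2-fold. In the comparison of Irf8 mutant and wild-type cDC2 these were 0%, 75%, 100% and 33.5%. Across these runs and those of the wild-type comparison, up to 10 unchanged genes were called. A simulated list change was recovered, and 0 of 23 unchanged lists were called. Simulated genes were drawn independently, so this does not test camera's calls for lists whose genes move together. In the real data the estimated correlation reached 0.577 for MHC class II genes in the Zeb2 mutant comparison.

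The alternatives were DESeq2 size factors or upper-quartile factors in place of TMM, no filter on low counts, a filter at a CPM of 1 in 2 libraries, DESeq2 1.42.0, limma-voom and only the 4 libraries compared. Others were the replicate number as a block, no robust estimation, a test against a 2-fold change, leaving out each library in turn, other thresholds for overlap and retention, and a window of 2000000 bases. Added after seeing the data were fits without each wild-type cDC1 library on the same 20631 genes, and fits with the length trend of each library removed by lowess (span 0.5 over genes of at least 10 CPM). No library and no column with counts was left out.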

Results

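RNA was sequenced from conventional dendritic cells (cDC), the cells that take up antigen and present it to T cells, sorted from mouse spleen. The 8 libraries formed 4 groups of 2: wild-type cDC1, wild-type cDC2, cDC1 of mice with the genotype Zeb2 -165(d1+2+3), and cDC2 of mice with the genotype Irf8 +32-/-. The Irf8 genotype names an enhancer of Irf8 that is missing on both copies, and the Zeb2 genotype names an altered enhancer of Zeb2. Neither label says that coding sequence was deleted. Each genotype other than wild type was profiled in 1 cell type, so no cDC2 of the Zeb2 mutant and no cDC1 of the Irf8 mutant enter the comparisons. The libraries, numbered replicate 2 and replicate 3 in every group, held 58611821 and 55638451 counts (wild-type cDC1), 57876701 and 57450844 (wild-type cDC2), 55147183 and 52658762 (Zeb2 mutant cDC1) and 54342518 and 49380686 (Irf8 mutant cDC2). Values below are counts scaled to library size (TMM-normalised CPM) as mean ± SD with n = 2 per group, and adjusted p-values come from edgeR's quasi-likelihood test on 20631 genes unless another tool is named.

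Cell type separated the libraries far more than genotype. The first principal component held 58.8% of the variance and the next one 9.16%. Across genes, the correlation of log2 CPM was 0.963 to 0.976 in the 4 pairs of the same group, 0.964 to 0.974 in the 8 pairs of the same cell type with different genotypes, and 0.904 to 0.919 in the 16 pairs of different cell types. Genes are not independent replicates, so these correlations describe the libraries only. The wild-type cDC1 pair differed most within a group: its log2 difference between replicates had an SD of 1.03, against 0.80 to 0.89 in the other groups. In that pair, the difference between replicate 2 and replicate 3 followed gene length (Spearman's rho of -0.39 over 8399 genes with a mean of at least 10 CPM), while rho was -0.0001 in wild-type cDC2, 0.24 in Zeb2 mutant cDC1 and 0.14 in Irf8 mutant cDC2.

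Neither gene whose enhancer a genotype names passed the test between mutant and wild type in the cell type that was profiled. Irf8, the transcription factor on which cDC1 depend (ENSMUSG00000041515, chromosome 8, 120736358 to 120756694, GRCm38), was at 3452 ± 267 CPM in wild-type cDC1 and 3574 ± 191 CPM in Zeb2 mutant cDC1. In cDC2 it was at 115 ± 15.9 CPM in wild type and 133 ± 18.9 CPM in the Irf8 mutant, a log2 fold change of 0.21 (edgeR adjusted p = 0.914). Zeb2, a repressor associated with the cDC2 and monocyte lineages (ENSMUSG00000026872, chromosome 2, 44983632 to 45117395), was at 200.4 ± 0.177 CPM in wild-type cDC2 and 185 ± 17.9 CPM in Irf8 mutant cDC2. In cDC1, Zeb2 was at 2.10 ± 0.00934 CPM in wild type and 2.89 ± 0.922 CPM in the Zeb2 mutant, a log2 fold change of 0.46 (edgeR adjusted p = 0.477). Zeb2 had 121 to 192 counts per library in cDC1 and Irf8 5842 to 7623 in cDC2, far below the other cell type, so these levels check the cell type of each library. Of the genes within 1000000 bases, 6 near Zeb2 and 20 near Irf8 were tested in their own mutant, and 0 passed edgeR's test (unadjusted p under 0.05: 0 near either gene). Within 2000000 bases, 0 of 7 genes near Zeb2 and 0 of 53 near Irf8 passed, with 0 and 4 at an unadjusted p under 0.05. A test of enrichment near Irf8 has no meaning, since edgeR called 0 genes in that mutant.

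**Figure D1:**
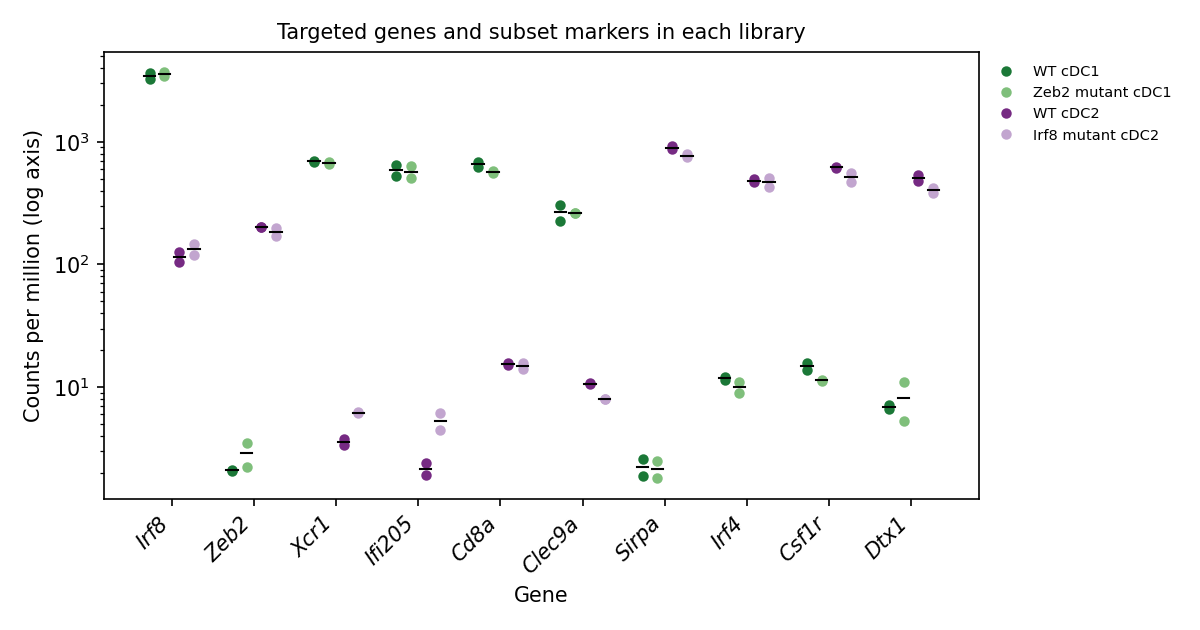
Expression of 10 genes in each of the 8 libraries, in TMM-normalised CPM on a log axis; dots are libraries and black bars are the means of the 4 groups (n = 2). Irf8 was at 3452 CPM in wild-type cDC1 and 115 CPM in wild-type cDC2, and Zeb2 at 2.10 and 200.4 CPM.

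Wild-type cDC1 and cDC2, compared to define the difference between the cell types, parted along their known marker genes. Xcr1, the chemokine receptor that marks cDC1, was at 694 ± 8.74 CPM in cDC1 and 3.59 ± 0.25 CPM in cDC2 (194-fold higher). Gcsam (2381-fold), Plpp1 (417-fold) and Ifi205 (269.9-fold) were also higher in cDC1, and Irf8 was 30.0-fold higher (log2 fold change 4.91, SE 0.174). Sirpa, the surface receptor that marks cDC2, was at 2.24 ± 0.502 CPM in cDC1 and 894 ± 30.6 CPM in cDC2 (399.8-fold lower in cDC1), and Zeb2 was 95.5-fold lower (log2 fold change -6.58, SE 0.228). All 26 cDC1 markers tested were higher in cDC1 (camera adjusted p = 5.7e-116), and 21 of 24 cDC2 markers were lower while 2 were higher (camera adjusted p = 2.8e-57). The counts adjusted over the list alone were the same, 26 higher for cDC1 markers, and 2 higher and 21 lower for cDC2 markers. Both list calls held with an estimated correlation (adjusted p = 0.000316 and 0.00525).

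The largest differences that passed the naming rule included genes outside the marker lists. In cDC1, Dkk3, which encodes a secreted protein of the Dickkopf family, was at 81.3 ± 6.52 CPM and had no count in wild-type cDC2 (at least 3015-fold higher, against a floor of 3 counts over the group). Gpr141b (1710-fold), P3h2 (611.5-fold), Gramd2 (508-fold), the Wnt receptor gene Fzd1 (276-fold) and Cltrn (at least 213-fold) were also higher. In cDC2, Tlr7, a sensor of single-stranded RNA, was at 118 ± 10.7 CPM (1520-fold lower in cDC1), and Dscam (1167-fold), the sodium channel gene Scn3a (871-fold), the lipid transfer protein gene Pltp (546-fold) and Zfp521 (at least 443-fold) followed. Sirpb1a (2133-fold), Sirpb1b (966-fold), Sirpb1c (523-fold) and Clec4a4 (1031-fold) were lower in cDC1 too, but belong to families of near-identical genes, and how shared reads were counted is not stated. Clnk, Adgrf5 and Tmem273 were named by the same rule with 1 to 3 counts in the lower group and get no fold. In all, edgeR called 2932 genes higher and 3287 lower in cDC1, of which 1634 and 2077 differed at least 2-fold. Without wild-type cDC2 replicate 2 the counts were 1721 and 2091, and without its replicate 3 the higher count was 1758.

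Pattern recognition receptors split between the cell types. Tlr3, the receptor for double-stranded RNA, was 108.5-fold higher in cDC1, whereas Tlr7, Tlr5 (423-fold) and Tlr8 (122-fold) were lower. Of 25 receptors tested, 3 were higher and 18 lower, also when adjusted over the list alone (camera adjusted p = 1.9e-08, and adjusted p = 0.0171 with an estimated correlation). Genes of the Notch-dependent, ESAM-high cDC2 were lower in cDC1 in 7 of 10 cases, 8 when adjusted over the list alone (camera adjusted p = 1.2e-16, and 0.00702 with an estimated correlation). Among them, the Notch target Dtx1 was at 509 ± 36.3 CPM in cDC2 (74.1-fold lower in cDC1) and Cd4 was 24.96-fold lower.

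Other lists differed by camera with its preset correlation of 0.01 and lost the call with an estimated one. For ESAM-low cDC2 genes, 3 were higher and 7 lower of 12, among them Csf1r (41.6-fold lower), Cd209a (41.5-fold lower) and Mgl2 (95.6-fold lower) (camera adjusted p = 1.6e-05; adjusted p = 0.179 with an estimated correlation). Of 40 transcription factors of dendritic cells, 6 were higher and 21 lower, 24 lower when adjusted over the list alone, with Irf4 at 11.8 ± 0.572 CPM in cDC1 and 483 ± 16.5 CPM in cDC2 (camera adjusted p = 2.6e-06; adjusted p = 0.0549 with an estimated correlation). Macrophage genes such as Adgre1 (60.9-fold) and Axl (17.9-fold) were lower in cDC1 in 11 of 14 cases, 12 adjusted over the list alone (camera adjusted p = 2.1e-09; adjusted p = 0.212 with an estimated correlation). Of 13 genes of plasmacytoid dendritic cells, 2 were higher and 7 lower, 8 lower over the list alone, including Lifr (39.6-fold), Spib (34.7-fold) and Siglech (27.4-fold) (camera adjusted p = 9.1e-05; adjusted p = 0.212 with an estimated correlation). Interferon response genes were lower in 19 of 28 cases and higher in 5, the same over the list alone, with Oas2 (123-fold), Rtp4 (57.0-fold) and Ifit1 (26.4-fold) lower (camera adjusted p = 1.4e-08; adjusted p = 0.154 with an estimated correlation).

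Genes of antigen presentation on MHC class I were higher in cDC1, which present antigen taken up from other cells to CD8 T cells. Of 19 tested, 9 were higher and 1 lower, the same when adjusted over the list alone, among them Pdia3 (3.49-fold), the peptide transporter gene Tap1 (2.69-fold) and the immunoproteasome gene Psmb9 (2.60-fold) (camera adjusted p = 0.000102; adjusted p = 0.216 with an estimated correlation). A list of immediate-early and stress genes, called immediate-early genes from here on, was lower in cDC1 (camera adjusted p = 0.00168, and 0.320 with an estimated correlation). In it 11 of 27 genes were lower, 16 when adjusted over the list alone, such as Fosb (788 ± 32 against 2546 ± 72 CPM) and Nfkbia (2.52-fold lower). The other 13 lists did not pass camera's test (adjusted p from 0.12 to 0.737). Their genes higher and lower numbered 4 and 9 of 16 for monocytes, 2 and 3 of 14 for B cells, 1 and 2 of 14 for T cells and 5 and 1 of 12 for NK cells. They numbered 0 and 1 of 11 for neutrophils, and 1 and 1 of 12 for erythroid cells and platelets. They numbered 5 and 7 of 19 for dendritic cell maturation, 2 and 4 of 12 for MHC class II, 5 and 7 of 23 for cytokines and chemokines, and 3 and 2 of 26 for the cell cycle. They numbered 7 and 1 of 20 for cholesterol synthesis, 5 and 5 of 18 for glycolysis and hypoxia, and 1 and 4 of 15 for early progenitors. Adjusted over the list alone, the counts changed to 4 and 10 for monocytes, 2 and 4 for B cells, 0 and 2 for T cells, 6 and 1 for NK cells and 0 and 1 for erythroid cells and platelets. They changed to 6 and 7 for maturation and for cytokines and to 1 and 5 for early progenitors. Single genes within them passed edgeR's test, including Il12b (534 ± 128 CPM in cDC1, 8.84-fold higher), Cxcl9 (19.4-fold higher), Vegfa (76.6-fold lower) and Csf3r (87.3-fold lower). For T cell, cytokine and glycolysis genes the median log2 fold change was above 0 (0.14, 0.11 and 0.20) and the mean and the test pointed down. MHC class II genes passed camera's test without wild-type cDC1 replicate 2 (adjusted p = 0.0416).

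In Zeb2 mutant cDC1, compared with wild-type cDC1 to see whether the enhancer's alteration left a mark on cDC1, 14 genes passed edgeR's test, 11 of them lower. Cd209a, a C-type lectin found on a part of cDC2 (ENSMUSG00000031494, chromosome 8, 3743397 to 3748984), was at 0.392 ± 0.0193 CPM in the mutant and 8.51 ± 4.22 CPM in wild type (21.7-fold lower, adjusted p = 0.00322). The prostaglandin-degrading enzyme gene Hpgd fell from 23.6 and 18.4 CPM in the wild-type libraries to 6.02 and 6.20 CPM in the mutant. Tnf, which encodes the cytokine tumour necrosis factor, fell from 77.0 ± 5.81 to 32.1 ± 0.546 CPM. Hpgd was also lower in Irf8 mutant cDC2 (log2 fold change -0.88), not past edgeR's test but called by DESeq2 (adjusted p = 0.00047). The log2 fold change of Tnf there was 0.23. Fkbp5, a glucocorticoid-induced co-chaperone gene, rose from 29.2 ± 2.15 to 102 ± 14.8 CPM (3.49-fold, adjusted p = 0.0109).

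The other called genes were smaller changes or low counts. Tnfsf9, the ligand of the costimulatory receptor 4-1BB, fell from 38.1 ± 0.372 to 17.4 ± 0.64 CPM, and the membrane protease gene St14 from 11.8 ± 0.243 to 5.49 ± 0.196 CPM. H2-M2 fell from 17.1 ± 1.71 to 5.24 ± 0.611 CPM and Apol7c from 561.5 ± 21.6 to 319 ± 8.35 CPM. H2-M2 and Apol7c belong to multigene families, as does Skint3. The kinase adaptor gene Pag1 rose from 6.10 ± 0.613 to 13.4 ± 0.826 CPM, and Lifr, which encodes the receptor of leukaemia inhibitory factor, from 1.01 ± 0.0437 to 3.19 ± 0.0196 CPM. Skint3 (6.41-fold lower), Abca9 (11.1-fold lower) and Nxpe5 (7.65-fold lower) stayed under 5 CPM in both groups. They and Lifr lie outside the rule for top genes, and Skint3, Abca9 and Nxpe5 were named after their values were seen because they belong to the called set. In wild-type cells, 8 of the 11 lower genes were higher in cDC2 than in cDC1, as were Fkbp5, Lifr and Pag1 among the genes that rose.

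**Figure D2:**
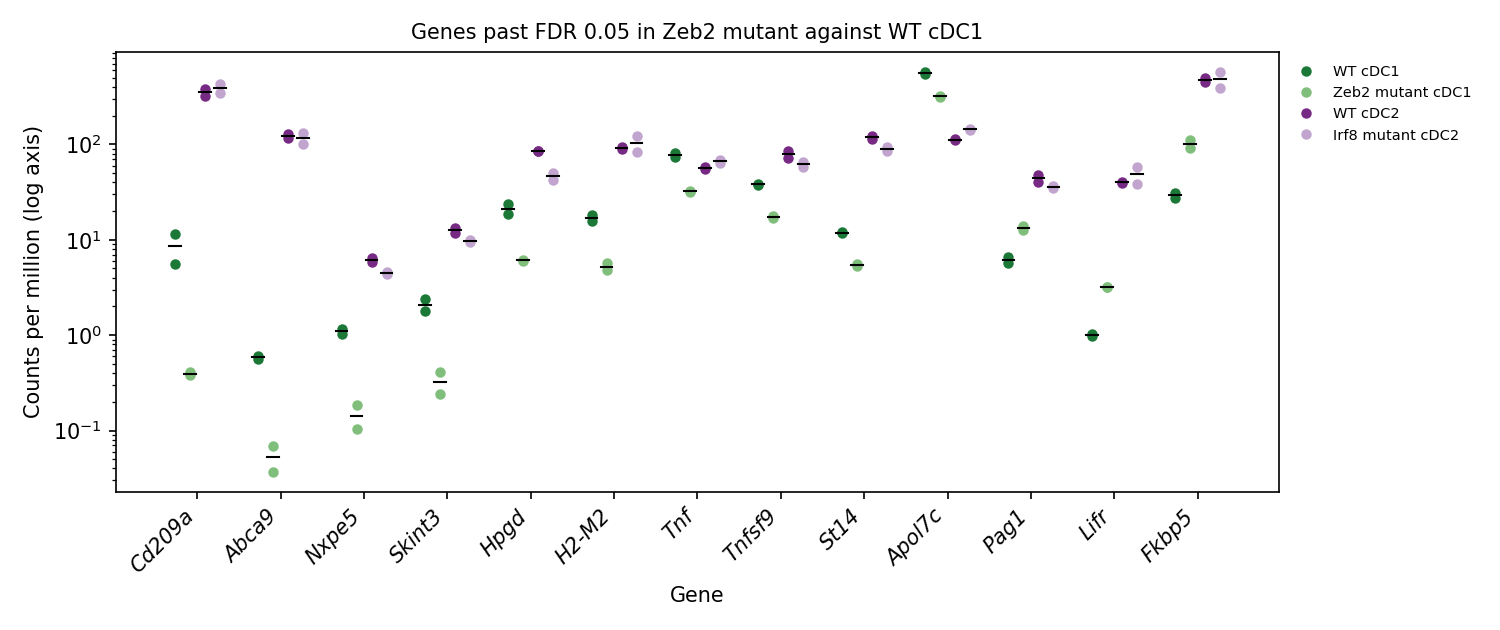
Expression of 13 of the 14 genes called between Zeb2 mutant and wild-type cDC1 in each library, in TMM-normalised CPM on a log axis; dots are libraries and black bars are group means (n = 2). Cd209a was at 0.392 CPM in Zeb2 mutant cDC1, 8.51 CPM in wild-type cDC1 and 352.8 CPM in wild-type cDC2.

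These counts rested on single libraries. Without wild-type cDC1 replicate 3, edgeR called 755 genes higher and 323 lower in the Zeb2 mutant (666 and 369 on the same 20631 genes), and without replicate 2 it called 11 and 22 (3 and 17 on the same genes). Without Zeb2 mutant replicate 2 it called 4 and 2, without replicate 3 5 and 4, and without 1 or the other wild-type cDC2 library 1 gene higher. Hpgd kept its call with any 1 library left out (edgeR adjusted p of at most 0.0453). Cd209a and Tnf lost theirs without Zeb2 mutant replicate 2 (0.0883 for both by edgeR) or replicate 3 (0.0622 for both), and Fkbp5 without wild-type cDC1 replicate 2 (0.0536). Of the 14 genes, 3 and 4 stayed called without Zeb2 mutant replicates 2 and 3, 11 and 14 without wild-type cDC1 replicates 2 and 3, 9 without 1 or the other wild-type cDC2 library, and 11 without 1 or the other Irf8 mutant library. The log2 fold changes also followed gene length (Spearman's rho of 0.48 over 8399 genes), and with the length trend of each library removed 9 of the 14 genes stayed called, while H2-M2, Tnfsf9, Lifr, Apol7c and Pag1 were lost.

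The cDC1 program was not among the gene groups that shifted in Zeb2 mutant cDC1. Of 26 cDC1 markers 0 passed edgeR's test and 1 did adjusted over the list alone (camera adjusted p = 0.458), with Xcr1 at 673 ± 20.6 CPM and Clec9a at 264 ± 0.176 CPM against 694 ± 8.74 and 267 ± 56.7 CPM in wild type. Immediate-early genes were lower as a list, with 0 of 27 past the test over all genes and 12 lower adjusted over the list alone (camera adjusted p = 4.0e-15, and 0.1296 with an estimated correlation). Dusp2 was at 106 ± 18.1 against 201 ± 35.2 CPM and Fosb at 509 and 492 CPM in the mutant libraries against 788 ± 32.0 CPM. Their summed CPM was 20580 and 19280 in the mutant libraries (replicates 2 and 3) and 26840 and 29030 in wild type. Cytokines and chemokines were lower as a list, 2 of 23 over all genes and 10 adjusted over the list alone, with Tnf and Tnfsf9 called and Ccl22 at 22.5 ± 4.63 against 46.9 ± 6.79 CPM (camera adjusted p = 1.3e-14; adjusted p = 0.1296 with an estimated correlation). Their summed CPM was 4724 in wild-type replicate 2 and 3005 in replicate 3, against 2642 and 2897 in the mutant.

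Markers of cDC2 were lower as a list too, with Cd209a called of 24 and 7 lower adjusted over the list alone (camera adjusted p = 3.7e-09), as were ESAM-low cDC2 genes (1 of 12, and 3 over the list alone; camera adjusted p = 1.2e-08). Both lists had an adjusted p = 0.1296 with an estimated correlation. Members include Klf4 at 59.4 ± 3.75 against 94.4 ± 6.70 CPM, and the summed CPM of the cDC2 markers was 960 and 1261 in the mutant against 1646 and 1059 in wild type. Lower as lists were also dendritic cell maturation (0 of 19, and 5 over the list alone; camera adjusted p = 1.7e-07, and adjusted p = 0.2195 with an estimated correlation) and cholesterol synthesis (0 of 20, and 1 over the list alone; camera adjusted p = 1.1e-06, and 0.1296). MHC class II (camera adjusted p = 0.000367, and 0.387 with an estimated correlation), MHC class I (0.00171, and 0.297) and ESAM-high cDC2 genes (0.0176, and 0.161) were lower with 0 genes called and 1, 1 and 3 lower over the list alone. Camera's call of MHC class II was lost without wild-type cDC1 replicate 2 (adjusted p = 0.139) or Zeb2 mutant replicate 2 (0.0771), and that of ESAM-high cDC2 genes without wild-type cDC1 replicate 2 (0.104), its replicate 3 (0.0785) or Zeb2 mutant replicate 3 (0.209).

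Transcripts of neutrophils were higher as a list in Zeb2 mutant cDC1, with 0 of 11 past edgeR's test and 3 higher adjusted over the list alone (camera adjusted p = 2.5e-08; adjusted p = 0.1296 with an estimated correlation). The granule protein gene Ngp was at 30.8 ± 7.43 against 2.21 ± 3.13 CPM and Elane, which encodes neutrophil elastase, at 8.40 ± 0.0396 against 0.665 ± 0.674 CPM. The list's summed CPM was 98.8 and 139 in the mutant libraries against 15.3 and 1.51 in wild type. Early progenitor genes (0 of 15, and 3 higher and 1 lower over the list alone; camera adjusted p = 0.00762, and 0.1296 with an estimated correlation) share Elane and Mpo with that list. Erythroid and platelet genes (camera adjusted p = 0.000757, and 0.297 with an estimated correlation), T cell genes (0.00171, and 0.4075) and interferon response genes (0.0355, and 0.4536) were higher as lists with 0 genes called over all genes or over the list alone. Camera's calls of the last 3 lists rested on single libraries. Erythroid and platelet genes lost theirs without wild-type cDC1 replicate 3 (adjusted p = 0.290), T cell genes without that library (0.2725) or Zeb2 mutant replicate 2 (0.0795), and interferon response genes without wild-type cDC1 replicate 2 (0.0866) or Zeb2 mutant replicate 2 (0.888). The remaining lists did not pass camera's test, though B cell genes did without wild-type cDC1 replicate 2 (adjusted p = 0.0343) or Zeb2 mutant replicate 3 (0.0349) and cell cycle genes without Zeb2 mutant replicate 2 (0.0261). For transcription factors, plasmacytoid, monocyte and macrophage genes the median, mean and test differed in sign.

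In Irf8 mutant cDC2, compared with wild-type cDC2 to see whether loss of the enhancer altered cDC2, 0 genes passed edgeR's test, with 1313 at an unadjusted p under 0.05. DESeq2 called 75 genes higher and 74 lower, and limma-voom 1 and 2. The smallest adjusted p-value in edgeR was 0.0508, shared by 7 genes, which are named here after their values were seen. Among these, Il12b, a subunit of interleukin 12, was at 147 ± 7.05 against 60.3 ± 5.12 CPM, and Wdfy1, an adaptor of Toll-like receptor signalling, at 25.1 ± 1.14 against 8.46 ± 1.13 CPM. The transcription factor genes Klf4 (226 ± 15.4 against 444 ± 34.9 CPM) and Fosb (1382 ± 79.8 against 2546 ± 72 CPM) and the fatty acid receptor gene Ffar4 (2.44 ± 0.295 against 7.37 ± 0.148 CPM) were at lower levels in the mutant. Gm36723 and the immunoglobulin segment Igkv5-39 complete the 7. In simulated data of the same depth, 75% of genes at 10 CPM or more that were changed 2-fold were recovered in this comparison, and 0% of those changed 1.5-fold.

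Single libraries moved this count as well. Without Irf8 mutant replicate 3 edgeR called 16 genes higher and 4 lower, without wild-type cDC1 replicate 2 18 and 10 (4 and 4 on the same genes), and without its replicate 3 10 and 10 (8 and 7). Without 1 or the other Zeb2 mutant library it called 1 and 1, and without 1 or the other wild-type cDC2 library 3 lower.

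Immediate-early genes were lower as a list in Irf8 mutant cDC2, with 0 of 27 past the test over all genes and 13 lower adjusted over the list alone (camera adjusted p = 1.5e-22, and 0.1384 with an estimated correlation). The list, which also covers stress genes, had a mean log2 fold change of -0.73 and a median of -0.50. Egr1 was at 464.5 ± 143 against 1017 ± 45.7 CPM and Nr4a1 at 4514 ± 834 against 7212 ± 412 CPM, and the list's summed CPM was 26170 and 30200 against 44610 and 38590. The maturation list was higher, with 4 of 19 higher over the list alone and Cd86, a costimulatory ligand, at 361 ± 106 against 181 ± 1.74 CPM (camera adjusted p = 6.1e-05; adjusted p = 0.374 with an estimated correlation). Neutrophil transcripts were higher (1 of 11 over the list alone; camera adjusted p = 6.1e-05; adjusted p = 0.256 with an estimated correlation), with a summed CPM of 152 and 79.3 in the mutant against 39.2 and 58.8 in wild type.

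Markers of cDC1 were higher as a list in Irf8 mutant cDC2, with 7 higher and 3 lower of 26 adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0183, and 0.1798 with an estimated correlation). The list was mixed, with 13 of 26 members above 0 and a median log2 fold change of 0.06 (mean 0.24). Lower as lists were cDC2 markers (2 of 24 over the list alone; camera adjusted p = 0.00299, and 0.377 with an estimated correlation), ESAM-high cDC2 genes (1 of 10; 0.00497, and 0.1798) and transcription factors of dendritic cells (5 lower and 2 higher of 40; 0.00299, and 0.1798). ESAM-low cDC2 genes did not pass (median log2 fold change 0.10, 7 of 12 above 0; camera adjusted p = 0.508, pointing down), but were called lower without Irf8 mutant replicate 2 (camera adjusted p = 0.0276). In these lists, lymphotoxin gene Ltb was at 125.5 ± 27.5 against 228 ± 22.2 CPM and Dtx1 at 400.4 ± 26.4 against 509 ± 36.3 CPM. Early progenitor genes (camera adjusted p = 0.0130, and 0.1798 with an estimated correlation) and cell cycle genes (0.0335, and 0.594) were higher. MHC class II (camera adjusted p = 0.0259, and 0.594), MHC class I (0.0353, and 0.561) and NK cell genes (0.0372, and 0.594) were lower. In these 5 lists 0 genes were called over all genes and 1, 0, 0, 0 and 0 over the list alone. Single libraries decided many of these list calls too. Without wild-type cDC2 replicate 2, camera's adjusted p was 0.2285 for cDC1 markers, 0.233 for cell cycle and 0.117 for MHC class II genes, and without its replicate 3 it was 0.0894 for cell cycle, 0.0819 for MHC class I and 0.313 for NK cell genes. Without Irf8 mutant replicate 3 it was 0.277 for cDC2 markers, 0.0870 for early progenitor, 0.396 for cell cycle, 0.0952 for MHC class II, 0.396 for MHC class I and 0.390 for NK cell genes. Without its replicate 2 it was 0.0625 for maturation, while 19 lists were called instead of 12. Without wild-type cDC1 replicate 3 it was 0.0588 for cDC1 markers and cell cycle genes and 0.0543 for NK cell genes, and without its replicate 2 it was 0.0525 for NK cell genes. For ESAM-low, B cell and T cell genes, which did not pass, the median, mean and test differed in sign.

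Mutant cDC1 and mutant cDC2, set against each other to see how much of the wild-type difference was present in cells of these genotypes, differed along the same markers. All 26 cDC1 markers were higher in Zeb2 mutant cDC1 than in Irf8 mutant cDC2 (camera adjusted p = 4.0e-115), such as Gcsam (1033-fold), Tlr3 (295-fold) and Itgae (187-fold), and Irf8 was 26.8-fold higher. Of 24 cDC2 markers 21 were lower and 1 higher (camera adjusted p = 6.7e-63), with Cd209a 987-fold, Clec4a4 848-fold and Zeb2 63.9-fold lower. Dkk3 (1343-fold), Gpr141b (1265-fold), Gramd2 (972-fold), Fzd1 (372-fold), P3h2 (331-fold), Trabd2b (303-fold) and Clnk (236-fold) were among the genes most increased in mutant cDC1. Abca9 (2200-fold), Scn3a (994-fold), Bmp8a (at least 202-fold) and Tarm1 (at least 196.5-fold) were among the most reduced.

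In all, edgeR called 2646 genes higher and 3104 lower in this comparison, 1484 and 2087 of them at least 2-fold. Without Zeb2 mutant replicate 2 the higher count was 1745, without its replicate 3 1681, and without Irf8 mutant replicate 2 the lower count was 2051. Of the 24 lists 13 passed camera's test and 4 kept the call with an estimated correlation: cDC1 markers (adjusted p = 0.000321), cDC2 markers (0.00662), ESAM-high cDC2 genes (8 of 10 lower; 0.00662) and pattern recognition receptors (3 higher and 17 lower of 25; 0.0225). Adjusted over the list alone, 2 cDC2 markers were higher and 9 ESAM-high cDC2 genes lower, and the other counts of these 4 lists were the same. The 9 that lost it with an estimated correlation were ESAM-low cDC2, interferon response, transcription factors, plasmacytoid, macrophage, MHC class I, maturation, cytokine and immediate-early genes (adjusted p from 0.1133 to 0.4543 with an estimated correlation). Camera also called NK cell (adjusted p = 0.0478) and MHC class II genes (0.0318) without Zeb2 mutant replicate 3, and monocyte genes (0.00205) without Irf8 mutant replicate 3. For neutrophil, erythroid and platelet, glycolysis and early progenitor genes, which did not pass, the median, mean and test differed in sign.

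Across the 6219 genes called between the wild-type cell types, the log2 fold changes between the mutant cell types had the same sign in 97.7% and correlated across genes with Pearson's r of 0.906 (Spearman's rho 0.941, slope 0.840). These comparisons share no library. Of those genes 4406 (70.8%) were also called in the same direction between the mutant cell types and 11 in the opposite direction. Over all 20631 tested genes, not selected by a call in wild type, 78.0% had the same sign and r was 0.654, and of the 5750 genes called between the mutant cell types 130 had the opposite sign in wild type. The genes called higher in both numbered 2037, against 376 if the calls were independent, and those lower in both 2369 against 494.5. Both comparisons use the same estimated spread of each gene, so the numbers for independent calls are too low as a reference.

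The effects of both genotypes were also set against each other directly, to see whether the same genes responded in cDC1 of the Zeb2 mutant and cDC2 of the Irf8 mutant. Across all tested genes their log2 fold changes had a Pearson's r of 0.0011, and 0.0563 over the 8399 genes with at least 10 CPM. No gene was called in both, since edgeR called 0 in the Irf8 mutant; 3 were shared without wild-type cDC1 replicate 3, and 1 without its replicate 2 or without wild-type cDC2 replicate 2. At an unadjusted p under 0.01, 17 genes were higher in both against 3.07 if independent, and 13 lower in both against 2.30. Both comparisons use the same estimated spread of each gene, which can raise such overlap by itself. These numbers therefore do not decide on a shared response, and overlap in opposite directions was not counted. The effects differed by edgeR's test of the difference for 4 genes, Cd209a, Tnf and Gp2 among them, each with a lower value in the Zeb2 mutant's effect, and 0 genes differed the other way (1573 genes at an unadjusted p under 0.05; DESeq2 called 81 and 87, limma-voom 0 and 3). Gp2, a receptor for bacteria on antigen-sampling epithelium, was at 32.1 ± 1.15 CPM in Zeb2 mutant and 65.3 ± 4.04 CPM in wild-type cDC1. Part of its difference was a higher level in Irf8 mutant cDC2 (DESeq2 log2 fold change 0.92, adjusted p = 0.00309), and edgeR called Gp2 in neither mutant. Without wild-type cDC1 replicate 3, 541 genes differed upwards and 164 downwards (364 and 166 on the same genes), and without its replicate 2, Zeb2 mutant replicate 3 or Irf8 mutant replicate 3 1 upwards each, and 2 without wild-type cDC2 replicate 3. The downward count was 0 without wild-type cDC2 replicate 2, without 1 or the other Zeb2 mutant library or without Irf8 mutant replicate 2, 2 without wild-type cDC2 replicate 3, and 9 without Irf8 mutant replicate 3.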

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

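Of the tests in this part, those on cells of another type, on flanking DNA, on normalization and on the length trend's removal were chosen only after the result was seen; those on handling and on length-matched genes were set before it. The 3 genes here stand out because edgeR's test found the Zeb2 mutant's effect in cDC1 different from the Irf8 mutant's effect in cDC2. The difference of log2 fold changes was -4.57 for Cd209a (adjusted p = 0.0250). It was -1.95 for Gp2 (adjusted p = 0.0350) and -1.49 for Tnf (adjusted p = 0.0350). All 3 lost the call without wild-type cDC2 replicate 2, Zeb2 mutant replicate 2 or 3, or Irf8 mutant replicate 2 (edgeR adjusted p from 0.0857 to 0.2747). They also lost it without wild-type cDC2 replicate 3 (0.0741 for Cd209a and Gp2 and 0.191 for Tnf), and Gp2 and Tnf without Irf8 mutant replicate 3 (0.0596 and 0.0762).

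Of the 11 genes lower in Zeb2 mutant cDC1, 8 are higher in wild-type cDC2, so cDC2 in the wild-type cDC1 sort are a candidate explanation, tested in several ways. The first test favoured it: the share that 25 abundant cDC2 genes imply in wild-type cDC1 had a median of 1.35% and an upper quartile of 2.4031%, above the smallest share needed, 0.4315% for Abca9; as such levels also hold the transcripts of cDC1 themselves, they set no lower limit on cDC2. A test on the drop of the same genes from wild type to mutant, and its bootstrap limit, were chosen after that outcome. The drop had a median of 0.0658% and an upper quartile of 0.4106% (bootstrap limit 0.5509%), with 9 of the 25 genes higher in the mutant. The 25 genes were chosen at 100 CPM or more in cDC2 and at least 32-fold over cDC1, leaving out the 8 lower genes. That rule limits in advance how far they can drop, so no conclusion is drawn from the drop alone. A share of cDC2 adds to every abundant cDC2 gene, however. The whole wild-type cDC1 levels of 4 of the 25, Sirpb1a, Tlr7, Dscam and Sirpa, allow at most 0.047%, 0.0657%, 0.0857% and 0.2501%. Their upper limits, corrected for the 25 genes, reach 0.298%, against a need of at least 0.3855% for Abca9 in single libraries. This test, set last, argues against this source for Abca9 and for the 7 genes that need 2.30% to 26.3%. A local effect of flanking DNA on the called genes is argued against by 0 of the 14 lying within 20000000 bases of Zeb2 or elsewhere on its chromosome. Of the called genes, Fkbp5, Tnf and H2-M2 lie between 28399094 and 37483552 on chromosome 17, and Tnfsf9 lies at 57105325 on it. Whether that grouping has a cause was not tested. Position says nothing on flanking DNA that acts on genes elsewhere. An effect of the Zeb2 genotype on cDC1 stays open as a hypothesis, beside such flanking DNA. A part of cDC2 rich in these transcripts and poor in those 4 stays open too, and none of these was tested.

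The list of immediate-early and stress genes was lower in both mutants, with medians of -0.45 and -0.50, and 22 of the 27 were lower in both. In either mutant 0 of 27 genes passed edgeR's test. Camera's calls were lost with an estimated correlation (adjusted p = 0.1296 and 0.1384), while fry called the list in both (fry adjusted p = 0.0334 and 0.0367). The 3 scalings differed too little to decide on normalization (highest median -0.4484), but 1 factor per library moves all genes alike, and the list's upper quartile minus the median of 8399 genes was at most -0.1708, which argues against it. Gene length as the whole change is argued against by the higher of the upper quartiles after the length trend was removed, -0.1497 (medians -0.37 and -0.47), but a part stays open, since genes matched in length and level had a median of -0.1414 in the Zeb2 mutant and -0.03 in the Irf8 mutant. Handling that differed between wild-type and mutant samples cannot be told apart from a shared effect of genotype. The members' changes correlated with Pearson's r of 0.7135 (Spearman's rho 0.446, permutation p = 0.00013, 100000 resamples), which both predict. The permutation treats genes as independent, though they are not, so its p does not measure the spread between samples. Whether wild-type and mutant samples were prepared together is not given in the sources used here. Genes induced while cells are prepared may thus differ for either reason.

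Transcripts of neutrophils were higher in Zeb2 mutant cDC1, a list with 0 of 11 genes past edgeR's test, whose call by camera was lost with an estimated correlation (adjusted p = 0.1296). Both mutant libraries lay above both wild-type libraries for 8 of the 11 genes (16.7% by chance for a single gene), and 0 lay the other way. Members of a higher list lie above wild type whatever the source, and they move together (estimated correlation 0.2565), so this number does not decide whether RNA or cells from neutrophils are the source, which stays open. In Irf8 mutant cDC2 the number was 7, and Ngp was the most abundant in Zeb2 mutant cDC1 at 30.8 CPM; the gates that would remove neutrophils are not given in the sources used here. Early progenitors, whose list shares Elane and Mpo, stay open as another source, and no biological explanation was tested.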

How the results depend on the processing

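Removing each library's length trend and leaving wild-type cDC1 libraries out on the same 20631 genes were chosen after seeing the data; all other alternatives were planned. The wild-type and mutant comparisons of cDC1 with cDC2 kept their counts within 1.5 times under every alternative except a test against a 2-fold change and some omissions of a library. That test called 698 higher and 1145 lower genes in wild type, 640 and 1189 between mutants, 0 and 2 in the Zeb2 mutant, and 0 lower for the difference of effects, as its construction asks for larger changes. All 14 genes called in the Zeb2 mutant kept their direction under each alternative, but the number of calls moved. Higher and lower genes were 258 and 219 without a filter, 151 and 137 with DESeq2, 8 higher with limma-voom, 1 higher with DESeq2 size factors, 0 and 2 with only the 4 libraries compared, and 1 higher with the length trend removed. Of the 14 genes limma-voom called 6, without Cd209a, and the fit of only the 4 libraries called 1, without Hpgd, Cd209a, Tnf and Fkbp5. In the Irf8 mutant they were 125 and 74 without a filter, 75 and 74 with DESeq2, 4 and 3 with DESeq2 size factors, 4 and 1 with upper-quartile factors, 4 and 3 with the CPM filter, 1 and 2 with limma-voom, 3 and 3 with only the 4 libraries compared, and 2 higher with the length trend removed. For the difference of effects they were 139 and 167 without a filter, 81 and 87 with DESeq2, and 1 lower with the replicate number as a block; differences between replicates 2 and 3 correlated between groups by only -0.0255 to -0.0015, which gives no sign of a source of variation shared by number. Without a filter 43631 genes were tested, and the common biological coefficient of variation was 0.389 against 0.286 in the main fit. Apart from the test against a 2-fold change, the cause of these changes was not tested. On the same genes, omitting wild-type cDC1 replicate 3 gave 666 and 369 in the Zeb2 mutant, 8 and 7 in the Irf8 mutant and 364 and 166 for the difference, and omitting replicate 2 gave 17 lower, 4 and 4, and 1 higher. Over the 8 omissions of 1 library, each refiltered and with the lone sample of a group assumed to vary like the others, higher and lower counts ranged from 1721 to 3171 and 2091 to 3634 (wild type), 1681 to 3466 and 2051 to 3648 (mutants), 1 to 755 and 2 to 323 (Zeb2 mutant), 0 to 18 and 0 to 10 (Irf8 mutant), and 0 to 541 and 0 to 164 (difference). Lists called by camera ranged from 11 to 12 (wild type), 13 to 15 (mutants), 11 to 14 (Zeb2 mutant), 9 to 19 (Irf8 mutant) and 5 to 10 (difference). With an estimated correlation they numbered 4, 4, 0, 0 and 0, and by fry 4 in the Zeb2 mutant, 3 in the Irf8 mutant and 0 for the difference. Fry called immediate-early and ESAM-high cDC2 genes lower and early progenitor genes higher in both mutants (fry adjusted p from 0.0149 to 0.0367). In the Zeb2 mutant it also called cholesterol genes lower (fry adjusted p = 0.0334). Without Irf8 mutant replicate 2, monocyte (camera adjusted p = 0.0223), macrophage (0.00912) and erythroid and platelet genes (0.00912) were called lower in the Irf8 mutant, and without its replicate 3 all 3 were called higher (0.00760, 0.00141 and 1.1e-14), the direction they had, not past the test, with all libraries. Those 3 values were the lowest over all omissions and the highest were 0.986, 0.943 and 0.265; the cause was not tested. For the wild-type difference found between mutants, r ranged from 0.833 to 0.902, the slope from 0.639 to 0.880, the same sign from 93.0% to 98.7% and the share also called from 57.2% to 85.7% over omissions. Over all tested genes these were 0.654, 0.674, 78.0% and 27.2%, and over genes changed at least 2-fold the last 2 were 98.3% and 79.7%. Genes shared by both effects ranged from 0 to 3 over omissions and numbered 30 at an unadjusted p under 0.01. The log2 fold change of Irf8 in Irf8 mutant cDC2 ranged from 0.03 to 0.34 and that of Zeb2 in Zeb2 mutant cDC1 from 0.10 to 0.76 over omissions. Low genes were recovered less often in simulated data. In the Zeb2 mutant comparison 34.5% of all genes changed 2-fold were recovered and 81.0% of those at 10 CPM or more. Depth and the number of libraries were not varied.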

Other observations

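The genes named in this part, the count of alternatives that call the genes nearest to the threshold and the comparison of replicates by gene length were chosen after the values were seen; the tests of lists and of the difference of effects were planned. In Zeb2 mutant cDC1, genes of cholesterol synthesis were lower as a list (1 of 20 above wild type by fitted value; camera adjusted p = 1.1e-06, and 0.1296 with an estimated correlation). Sqle, which encodes squalene epoxidase, was at 34.3 ± 0.20 against 49.6 ± 3.82 CPM. In Irf8 mutant cDC2 the list did not pass (camera adjusted p = 0.153).

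In Irf8 mutant cDC2, 0 of 26 cDC1 markers passed edgeR's test. Xcr1 was at 6.22 ± 0.0841 against 3.59 ± 0.25 CPM and Ifi205 at 5.32 ± 1.21 against 2.17 ± 0.328 CPM (edgeR adjusted p = 0.135 for both). DESeq2 called both higher (adjusted p = 0.00161 and 8.0e-06) and Tlr3 lower (0.00232). Tlr3 was at 1.23 ± 0.119 against 2.68 ± 0.68 CPM, while Cd8a was at 14.9 ± 1.06 against 15.5 ± 0.384 CPM and Clec9a at 8.05 ± 0.024 against 10.7 ± 0.102 CPM. Of the genes nearest to edgeR's threshold in this comparison, Ffar4, Wdfy1 and Igkv5-39 were called under 12 of the alternatives, Il12b under 11, Fosb and Klf4 under 10 and Gm36723 under 9.

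Itgae, the integrin CD103 of cDC1, was at 229 ± 42.3 CPM in Zeb2 mutant cDC1 and 108 ± 5.87 CPM in wild type (edgeR adjusted p = 0.0871). In the difference of both effects 7 lists passed camera's test, and 0 did with an estimated correlation or by fry: maturation, cytokine, ESAM-low cDC2, cDC2 marker and cholesterol genes pointed down, and T cell genes and transcription factors up. Camera's call of cDC2 markers was lost without wild-type cDC1 replicate 2 (adjusted p = 0.545), wild-type cDC2 replicate 3 (0.0549) or Zeb2 mutant replicate 3 (0.111). T cell genes lost theirs without wild-type cDC1 replicate 3 (0.325), Zeb2 mutant replicate 2 (0.0823) or Irf8 mutant replicate 3 (0.164), and transcription factors without Irf8 mutant replicate 3 (0.0637). Cholesterol genes lost theirs without wild-type cDC1 replicate 3 (0.0795), wild-type cDC2 replicate 2 (0.279), Zeb2 mutant replicate 3 (0.0800) or Irf8 mutant replicate 3 (0.0966). For ESAM-high cDC2, plasmacytoid, monocyte, erythroid and platelet, and glycolysis genes, which did not pass, the median, mean and test differed in sign. The libraries of wild-type cDC1 held the fewest and the most genes with a count, 25993 in replicate 2 and 32358 in replicate 3. Between them genes in the lowest quartile of length had a median log2 ratio of 0.25 (replicate 2 over replicate 3) and those in the highest -0.13.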
